A study of Mus musculus with 17 samples.

How the data were processed

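Eosinophils were sorted from CC10-IL13 transgenic mice, in which food containing doxycycline (Dox) switches on an interleukin-13 (IL-13) transgene. The mice carried a deletion of Pirb or were wildtype littermates. Pirb encodes paired immunoglobulin-like receptor B, an inhibitory receptor of myeloid cells. Per the labels' protocols, male and female mice aged 6 to 8 weeks were used, and Dox was fed for 2 weeks. Per the same protocols, the esophagus was digested with collagenase, while marrow was passed through a needle. Cells positive for CD45, Siglec-F and CCR3 were sorted from both. RNA was purified on RNeasy columns, amplified with the Nugen Ovation One-Direct system and labelled with the Nugen Encore Biotin Module, per the labels' protocols. The arrays were Affymetrix 1-colour arrays, and Affymetrix Expression Console is named in the submitters' processing notes, with no version. Whether its default summarization was used is not given in the sources used here.

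The values used were those of the series' value table, with 17 array columns and 33793 probe sets. They are log values that the authors deposited, taken here as log2, and no source used here states the log base. Each probe set had been centred before deposit. In 97.08% of probe sets a pair of middle values was equal and opposite, within a tolerance of 2e-05, which places 0 at the median of 18 arrays. The table holds 17 of them, and the series' design text says that 1 wildtype marrow replicate without Dox was dropped for low hybridization signal. The largest range of values within a probe set was 7.17. Because of the centring, a value gives the distance of an array from the median array and not the brightness of the probe set. Differences between groups are not changed by it. Any normalization between arrays by the authors is not given in the sources used here, and no column of the table was left unused.

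Gene names were taken from the platform annotation. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 8458 had none. Names were updated through Entrez identifiers in a reference gene table of the GRCm38.p6 assembly, which held 23328 of the 23521. No coordinates are printed, because the annotation's own build is not named. Probe sets with 1 symbol gave 22180 genes. For the 1082 genes with several probe sets, the mean of their values was used.

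The dim-probe filter and the choice of the brightest probe set per gene, fixed in advance, need brightness and could not be applied to centred values. All 22180 genes were therefore tested. Using the probe set with the lowest number was added as an alternative after the data were seen.

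Group labels and replicate numbers came from the sample titles. The 6 groups were marrow without Dox in wildtype (2 arrays) and knockout (3 arrays), marrow with Dox in wildtype and knockout (3 arrays each), and esophagus with Dox in wildtype and knockout (3 arrays each). The wildtype mice and the mice without Dox are the controls, per the series' design text. No label says whether replicates are separate animals or pools, so p-values measure only the spread between these samples. No 2 arrays of a group were duplicates, with the closest pair at r = 0.83 across genes and 0.0296% of values identical. The number of arrays limits the precision.

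All 17 arrays entered 1 linear model with 6 group means in limma 3.58.1 (R 4.3.3), with moderated variances from eBayes. The 10 contrasts were the knockout minus wildtype difference in each of 3 settings, its average over them, the Dox effect in marrow of each genotype, the esophagus minus marrow difference with Dox in each genotype, and the genotype by tissue and genotype by Dox interactions. Tests were two-sided, adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. Errors given with log2 differences are standard errors of that model, and errors given with group means are SDs. A single probe set value was compared with an exact permutation test of the difference in means.

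The 37 gene lists were fixed before the data were examined, as were the contrasts, the tests, the rule for naming genes and all but 2 of the alternatives. They covered eosinophil granule and identity genes, receptors, cytokine responses, mediators, metabolism, stress, proliferation, housekeeping genes, genes near the targeted gene on chromosome 7, and markers of other cell types that the tissue or the gate could hold. Of these lists, 36 had at least 5 measured members and were tested. The list of Y-linked genes and Xist had fewer and was not tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. The same test with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance, were run as alternatives. List p-values were adjusted over the 36 lists. Some genes belong to several lists, so list calls are not independent of one another. Members of a list that passed were counted after adjustment over all genes and after adjustment over the list alone.

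Named genes were Pirb, the gate genes Siglecf and Ccr3, the granule genes Epx and Prg2, the 10 largest called changes each way whose arrays did not overlap between groups, and up to 4 called members of each list. With fewer than 2 called members, up to 2 members with the largest moderated statistic were allowed. With fewer than 5 called genes in a contrast, the 5 with the smallest p were allowed. For interactions and the averaged contrast the 5 largest each way were taken. Predicted genes, olfactory and vomeronasal receptors, small RNA genes and antigen receptor segments were counted and not named. By chance, 10% of genes would have 3 arrays wholly apart from 3 others.

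Alternatives were a fold threshold, trend and robust moderation, only the groups of the contrast, array weights, the replicate number as a block, quantile normalization, median centring of each array, a Y-linked covariate for sex, the probe set with the lowest number, and leaving out each array in turn. Quantile normalization was run on the centred values and gives every array the same distribution. The centred values of esophageal arrays are wider than those of most marrow arrays. It therefore narrows the former and widens the latter by construction, and calls lost or gained under it are to be read with that limit. A fit without 1 outlying array was added after the data were seen. The same steps were tested on simulated data with 22180 genes, over 3 simulations per comparison. In each, 200 single genes were changed, and a further list of genes was shifted. Values were drawn independently for each gene, with the same SD in all arrays. The simulations therefore hold neither the wider spread of the outlying array nor correlation between genes, and the shares recovered may not hold for these data. For the genotype effect in the esophagus, 70.3% of genes changed by a log2 fold of 1 and 91.0% of those changed by a log2 fold of 2 were recovered, with a mean of 10.7 false calls. For the genotype effect in marrow with Dox the shares were 76.7% and 94.0%, for the Dox effect in wildtype marrow 67.3% and 93.0%, and for the tissue difference in wildtype 75.3% and 92.7%. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.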

Results

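Gene expression was measured on 17 Affymetrix arrays of eosinophils, the granulocytes that accumulate in the esophagus in allergic disease. The cells came from CC10-IL13 transgenic mice with or without Pirb, sorted from bone marrow or from the esophagus. Marrow eosinophils were studied without Dox (2 wildtype and 3 knockout arrays) and after 2 weeks of Dox (3 and 3). Esophageal eosinophils were studied with Dox only (3 and 3). Values are log2 distances from the median array of each probe set, so a value near 0 is the level of the middle array and not a low level. The log base, and any scaling between arrays before deposit, stay unknown.

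The array medians were close to 0 in most samples. In wildtype marrow without Dox they were -0.014 in replicate 1 and 0.000648 in replicate 3. Knockout marrow without Dox had -0.000697, 0.0128 and 0.202. The Dox marrow medians were -0.0391, -0.0295 and -0.000865 in wildtype, and -0.0497, -0.0342 and -0.0414 in knockout. Esophageal eosinophils had 0.0166, 0.131 and 0.0984 in wildtype, and -0.00574, -0.0106 and 0.0156 in knockout. Replicate 3 of knockout marrow without Dox stood apart from its group. Its values had an SD of 0.811, against 0.25 to 0.30 in the other marrow arrays and 0.50 to 0.59 in the esophageal arrays. Its mean correlation across genes was -0.0268 with its own group and 0.380 with the wildtype esophageal arrays. All arrays share 1 estimate of spread, so the counts of genes are also given without that array. Deviations from the group mean had SDs of 0.18 to 0.32 in esophageal arrays and 0.15 to 0.18 in Dox marrow arrays. Without the outlying array the shared spread may therefore be too small for esophageal groups, and their counts too high. Esophageal wildtype replicate 1 correlated more with the knockout esophageal arrays (r = 0.704 across genes) than with its own group (r = 0.593).

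**Figure D1:**
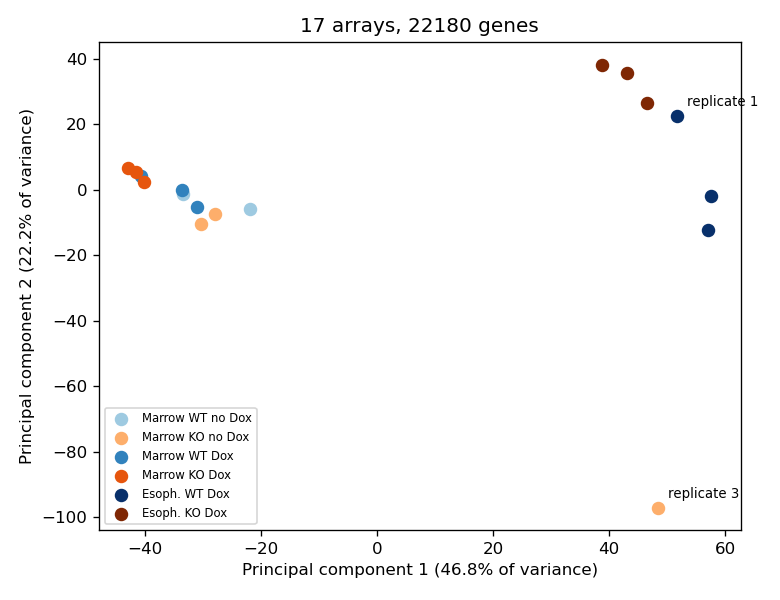
Each point is 1 of the 17 arrays on the first and second principal components of 22180 genes, with 46.8% and 22.2% of the variance, coloured by group. Esophageal arrays lie at 38.7 to 57.6 on the first component and 1 knockout marrow array without Dox lies at 48.4 and -97.2, apart from all others.

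Pirb encodes the inhibitory receptor that was deleted. Its centred value in esophageal eosinophils was 1.28 ± 0.77 (SD, n = 3) in wildtype and 1.00 ± 0.21 (SD, n = 3) in knockout. In marrow with Dox the means were -0.25 in wildtype and -0.40 in knockout, and without Dox they were 0.01 and -0.39. None of the genotype differences in Pirb passed the test. They were -0.28 ± 0.39 in the esophagus (exact permutation p = 0.9), -0.15 ± 0.39 in marrow with Dox (exact p = 0.6) and -0.40 ± 0.43 without Dox (exact p = 0.8), where the smallest exact p possible is 0.1. The last difference was 0.0055 without the outlying array, at -1.21. Whether the probes lie in the deleted part of the gene is not known, so the Pirb value checks nothing about the genotype labels. The Pira paralogs shared a probe set with other genes and are not reported singly. With Dox, the Pirb value was higher in the esophagus than in marrow, with the arrays of both tissues wholly apart. The difference was 1.53 ± 0.39 in wildtype (adjusted p = 0.0212) and 1.40 ± 0.39 in knockout (adjusted p = 0.0348). The wildtype call ended when only the groups compared were fitted (adjusted p = 0.0544), and the knockout call ended with median centring (adjusted p = 0.0604). The probe set that the Pira paralogs share was higher in the esophagus too, by 1.526 in wildtype and 2.598 in knockout. Whether the Pirb probes also read these paralogs was not tested. The rise, present in knockout as well, is therefore not shown for the intact Pirb transcript.

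The genotype effect in the IL-13-exposed esophagus is the question of the series title. Knockout eosinophils there had more Csf1, the growth factor of macrophages, than wildtype eosinophils, by 2.04 ± 0.22 (SE, n = 3 and 3, adjusted p = 0.00262). The centred mean of Csf1 was 3.13 ± 0.58 (SD) in knockout and 1.09 ± 0.10 in wildtype. Adamdec1, a secreted metalloprotease, rose by 2.11 ± 0.28 (adjusted p = 0.0120), and Ikzf2, the transcription factor Helios, by 2.26 ± 0.35 (adjusted p = 0.0228). Cxcl10, an interferon-inducible chemokine, rose by 1.16 ± 0.18, and Tnip3, which binds the NF-kB inhibitor A20, by 1.50 ± 0.24 (adjusted p = 0.0239 for both). Siglecf, the gate receptor that restrains eosinophil numbers, rose by 0.95 ± 0.16 (adjusted p = 0.0259). Genes lower in knockout included Clec4a1, a C-type lectin receptor, at -1.81 ± 0.33 (adjusted p = 0.0401), and Thbd, which encodes thrombomodulin, at -0.69 ± 0.11 (adjusted p = 0.0239).

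In all, 77 genes passed in the esophagus, 69 higher and 8 lower in knockout. Other large increases were in Etnk1, an ethanolamine kinase (2.43 ± 0.39), Zdhhc13, a palmitoyltransferase (2.10 ± 0.40), Tram1, of the endoplasmic reticulum translocation site (1.99 ± 0.33), and Chm, a Rab escort protein (1.85 ± 0.35). Phxr4 (2.49 ± 0.42), Coa5 (1.99 ± 0.37) and Jrkl (1.93 ± 0.28) rose too. Pmaip1, which encodes the death-promoting protein Noxa, rose by 1.66 ± 0.27, and Tgfbi, a matrix protein induced by TGF-beta, by 1.03 ± 0.18. Kif22, a mitotic kinesin, fell by 0.81, Nlrp5 by 0.52, Ncln by 0.46, the O-fucosyltransferase gene Pofut1 by 0.44 and Aldh3a1 by 0.39. For each gene named as changed, the 3 arrays of 1 genotype lay wholly apart from the 3 of the other, as 10% of genes would by chance. The naming rule required this of the largest changes, so it is no separate support for them. Granule genes and the second gate gene did not pass. Epx, the eosinophil peroxidase, differed by -0.06 ± 0.41, Prg2, the major basic protein, by 1.32 ± 0.35 (adjusted p = 0.154), and Ccr3, the eotaxin receptor, by 0.47 ± 0.56.

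The esophageal count depended on single arrays and on the scaling. Without the outlying marrow array, 763 genes passed, 389 higher and 374 lower, and all 77 were among them. That count may be too high, because the narrower marrow arrays then help set the shared spread. Leaving out wildtype replicate 1 gave 532, wildtype replicate 2 gave 30 and wildtype replicate 3 gave 44. Leaving out knockout replicate 1 gave 22 and knockout replicate 2 gave 36, all of them higher, so none of the 8 lower genes, Clec4a1 and Thbd included, passed without either array. Of the 22 genes followed singly, Csf1 and Adamdec1 kept their call whichever esophageal array was left out, and 20 lost it without at least 1 of the 6. After quantile normalization 2 genes passed, both higher, and none of the genes named above did. Csf1 was then 1.05 higher (adjusted p = 0.455) and Siglecf 0.71 higher (adjusted p = 0.797). That setting narrows the centred esophageal values by construction, so the lost calls do not decide whether these differences hold. With only the esophageal groups fitted 8 genes passed, Tgfbi among them (adjusted p = 0.0468). With the mean of the Y-linked genes Eif2s3y, Kdm5d and Uty as a covariate for sex, 7 genes passed, 6 of them among the 77, and 4 lists. Of the genes named as changed Csf1 alone kept its call (2.20, adjusted p = 0.0323), while Siglecf was at 0.97 (adjusted p = 0.229). All 77 differences kept their direction, with a median size of 1.29 and a median SE of 0.205 before, and 1.12 and 0.251 with the covariate. Uty and Kdm5d, named after their values were seen, had esophageal means of 0.14 and 0.39 in knockout and -0.74 and -0.95 in wildtype, with the arrays of the genotypes wholly apart. Neither passed (adjusted p = 0.129 and 0.218), and Eif2s3y was at 0.62 and 0.58. Xist, the RNA of the inactive X chromosome, was at -0.00176 in knockout and 0.15 in wildtype, with the arrays wholly apart too (adjusted p = 0.364). Mice of both sexes were used, and no label gives the sex behind a sample. Kdm5d was also low in the outlying marrow array (-1.66), so the covariate may follow array quality as well as sex.

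Of the 36 gene lists, 16 were called by camera in the esophagus and 4 of them also with an estimated correlation. Fry called 6. Eosinophil granule and identity genes were among the 4, with 22 of 26 members higher in knockout, a median of 0.34 and 1 member passing (4 when adjusted over the list alone). Their adjusted p was 2.93e-07, and 0.0223 with an estimated correlation. Chemoattractant receptors, integrins and adhesion genes had a median of 0.47 over 29 members, with adjusted p = 0.0196 with an estimated correlation. None passed over all genes, and adjusted over the list alone 5 were higher and 1 lower. The integrin gene Itgb3 was 1.47 ± 0.32 higher (adjusted p = 0.0717) and Selplg, which encodes the selectin ligand PSGL-1, 0.98 ± 0.28 higher (adjusted p = 0.185). Glycolysis and hypoxia genes had a median of 0.23 over 31 members, of which 5 were higher adjusted over the list alone and none over all genes. The glucose transporter gene Slc2a3 was 1.04 ± 0.21 higher (adjusted p = 0.0563), and adjusted p for the list was 0.0196 with an estimated correlation. NF-kB response genes, led by Tnip3, had a median of 0.28 over 31 members, with 1 passing (5 adjusted over the list alone), and adjusted p = 0.0196 with an estimated correlation. After quantile normalization the first 3 of these lists stayed called by camera (adjusted p = 0.00926, 0.00223 and 0.00156), and the NF-kB list did not (adjusted p = 0.0602).

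The remaining 12 called lists were higher in knockout by camera and lost their call with an estimated correlation. Inhibitory receptors had a median of 0.24 (adjusted p = 0.102 with an estimated correlation), activating receptors 0.13 (0.102) and redox genes 0.31 (0.0739). Immediate-early genes had a median of 0.30 (0.162), oxidative phosphorylation 0.23 (0.406), apoptosis and survival 0.05 (0.0515) and pattern recognition receptors 0.05 (0.0786). Matrix genes had a median of 0.02 (0.180), interferon response genes 0.01 (0.180), and housekeeping genes 0.15 (0.325). Cytokines and growth factors (0.102) had a median of -0.02, against the direction of their test, and 0.03 and 0.07 after quantile normalization and median centring. Csf1 was their 1 member passing, with 4 higher adjusted over the list alone, and Tnf, a proinflammatory cytokine, was 1.89 ± 0.40 higher (adjusted p = 0.0708). Neutrophil markers had a median of 0.28 (0.406), which became -0.07 after quantile normalization. Over all genes, 1 apoptosis gene (Pmaip1) and 1 matrix gene (Tgfbi) passed too. Adjusted over the list alone, 4 activating receptor, 4 immediate-early and 1 each of the inhibitory receptor, redox, matrix, interferon, apoptosis and pattern recognition genes were higher, and 1 redox and 1 immediate-early gene lower.

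Markers of monocytes and macrophages were not called in the esophagus, with a median of -0.17 over 18 members (adjusted p = 0.216). None of them passed over all genes, and 6 were lower adjusted over the list alone. Mrc1, the mannose receptor, was at -1.07 ± 0.24 (adjusted p = 0.0814) and C1qb, of complement C1q, at -0.61 ± 0.14 (adjusted p = 0.107). IL-4 and IL-13 response genes, which act through STAT6, had a median of -0.23 (adjusted p = 0.508), and 21 of 32 were lower. Fry, which tests the list on its own, called them lower (adjusted p = 0.0349). Genes near the targeted gene on chromosome 7 had a median of -0.13 over 31 members (adjusted p = 0.758), beside a median of -0.10 over all genes.

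**Figure D2:**
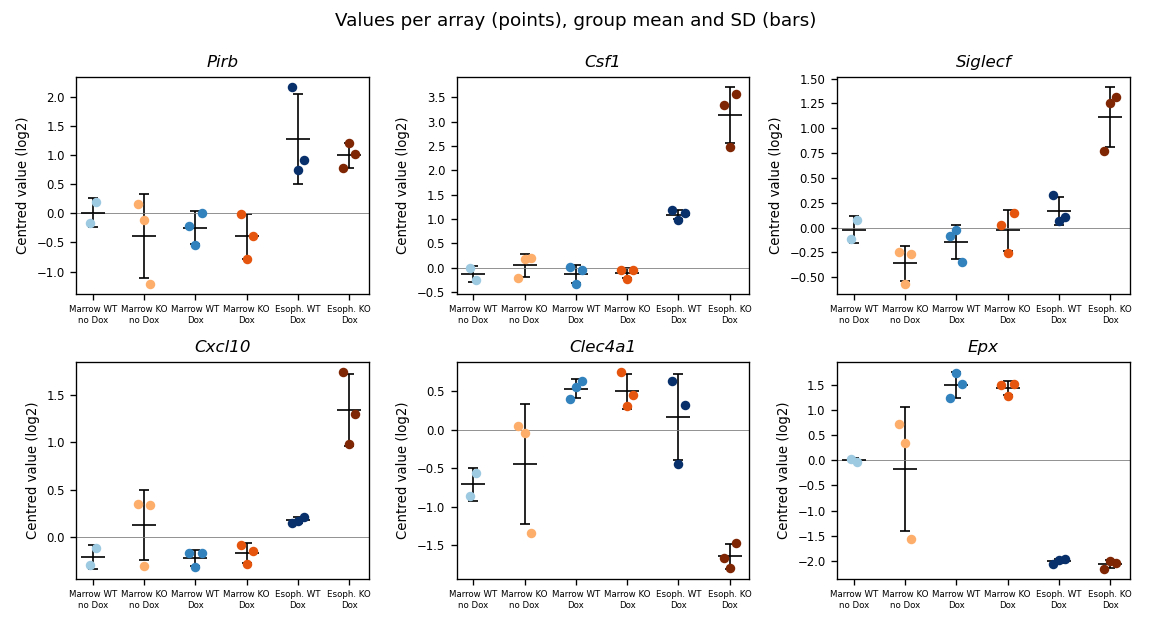
Centred log2 values of Pirb, Csf1, Siglecf, Cxcl10, Clec4a1 and Epx, with a point per array and bars for the mean and SD of each of the 6 groups. In the esophagus Csf1 averages 3.13 in knockout and 1.09 in wildtype, and Siglecf averages 1.11 and 0.17.

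In marrow with Dox, no gene passed between the genotypes by limma, and 407 had an unadjusted p under 0.05. If no gene differed, a share of 0.05 of the 22180 genes would have such a p, and 407 is fewer. Such counts in the other contrasts are to be read against the same share. The smallest p values were for Col14a1, a collagen, at 1.14 ± 0.16, Tmem141 at 1.08 ± 0.16 and Dnajb14, a heat shock cochaperone, at 0.74 ± 0.11 (SE, n = 3 and 3, adjusted p = 0.101 each). Med23, a Mediator subunit, differed by 0.69 ± 0.11 and Slc26a8 by 0.46 ± 0.08. Siglecf differed by 0.12, Epx by -0.06 and Prg2 by -0.02. Cell cycle genes were called higher in knockout by camera, with 28 of 38 members higher, a median of 0.17 and adjusted p = 0.0498. None of them passed over all genes or over the list alone, and adjusted p = 0.917 with an estimated correlation. No list was called after leaving out wildtype replicate 2 or 3 or any 1 of the knockout replicates, and leaving out wildtype replicate 1 gave 2. Without wildtype replicate 3, 1 gene passed, and without knockout replicate 1, 2 genes did. The count stayed at 0 without the outlying array, with 745 genes at an unadjusted p under 0.05.

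In marrow without Dox, neutrophil markers were called lower in knockout, with 16 of 17 members lower and a median of -0.84 (adjusted p = 5.78e-09, and adjusted p = 0.202 with an estimated correlation). Their members Stfa2l1, a stefin, and Olfm4, of neutrophil granules, were at -1.59 ± 0.39 and -1.19 ± 0.27. None passed over all genes, and 2 were lower adjusted over the list alone. Without the outlying array, which is 1 of the 3 knockout arrays here, the median was -0.07 (adjusted p = 0.0376). Cell cycle genes had a median of -0.40 (adjusted p = 0.365 with an estimated correlation) and oxidative phosphorylation genes -0.30 (0.448). Without that array these medians were 0.00 and 0.09. The 7 other lists called lower by camera were inhibitory receptors (-0.36), housekeeping genes (-0.37), activating receptors (-0.26), granule and identity genes (-0.11), lipid mediator genes (-0.09), chemoattractant receptors (-0.03) and glycolysis genes (-0.03). Their adjusted p was between 0.202 and 0.332 with an estimated correlation. Of the 10 lists only the neutrophil list was called without the outlying array, beside macrophage markers (0.21, adjusted p = 0.0376).

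No single gene passed between the genotypes without Dox by limma, and 1809 had an unadjusted p under 0.05. The smallest p values were for Extl2, a glycosaminoglycan transferase (-1.08 ± 0.17), Rnf138, a ubiquitin ligase (-0.91 ± 0.17), Sdhaf2, an assembly factor of succinate dehydrogenase (-1.29 ± 0.25), the sialyltransferase gene St3gal6 (-0.63 ± 0.12) and Stfa3 (-2.53 ± 0.51), each with adjusted p = 0.546 (SE, n = 3 and 2). The stefins are near-identical paralogs, so their single values are uncertain. Leaving out wildtype replicate 1 gave 6 genes and wildtype replicate 3 gave 5, where the lone array left is assumed to vary like the other groups. Leaving out knockout replicate 1 or the outlying replicate 3 gave 1 gene each. After quantile normalization 37 passed, 21 higher and 16 lower. Averaged over the 3 settings, 0 genes passed by limma, with 785 at an unadjusted p under 0.05, and no list was called by any of the 3 list tests. Camera called 13 lists without the outlying array, none with an estimated correlation. Leaving out another array without Dox gave 2 or 3 lists, and wildtype esophageal replicate 1 gave 8. Csf1 averaged 0.75 ± 0.13 (adjusted p = 0.578) and Cxcl10 0.51 ± 0.11 (adjusted p = 0.736). Dnajb14 was at 0.41 ± 0.07 and Suz12, of the Polycomb complex PRC2, at 0.42 ± 0.07 (adjusted p = 0.518 each), and Mthfs and Oser1 had 0.45 and 0.81. With the outlying array left out 2 genes passed. Leaving out other single arrays gave 2 (wildtype no-Dox replicate 1), 3 (wildtype no-Dox replicate 3), 1 (wildtype Dox replicate 2), 2 and 1 (knockout esophagus replicates 2 and 3).

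Dox feeding, which induces the transgene, raised Retnla in wildtype marrow eosinophils by 4.23 ± 0.56 (SE, n = 3 and 2, adjusted p = 0.0289). Retnla encodes a secreted protein induced by IL-4 and IL-13, and its centred mean went from -3.20 to 1.03. Psap, which encodes the lysosomal protein prosaposin, rose by 1.29 ± 0.16, and Lrp1, an endocytic receptor, by 1.00 ± 0.13 (adjusted p = 0.0261 for both). Mpzl1, a transmembrane protein that binds SHP-2, rose by 1.59 ± 0.23 (adjusted p = 0.0407), and Extl2 fell by 1.26 (adjusted p = 0.0294). Values of Epx (1.50 ± 0.46, adjusted p = 0.677), Hmox1, the heme oxygenase (1.59 ± 0.26, adjusted p = 0.0864), and Il1b (-2.52 ± 0.46, adjusted p = 0.128) did not pass. The prostaglandin-degrading enzyme gene Hpgd was at 1.61 ± 0.30 (adjusted p = 0.142).

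These 5 genes, 4 higher and 1 lower, were all that passed in wildtype, with 957 at an unadjusted p under 0.05. In each, the 3 Dox arrays lay wholly apart from the 2 without Dox. All 5 lost their call when only the groups compared were fitted, and with the Y-linked covariate Psap and Lrp1 kept theirs. With median centring 3 passed, all higher, and after quantile normalization 92 genes were higher and 34 lower. Once the outlying array was left out 33 passed, 27 higher and 6 lower, among them the 5 and Epx (adjusted p = 0.00447), Hmox1 (0.0115) and Il1b (0.0240). Leaving out no-Dox replicate 1 gave 14 genes, 1 higher and 13 lower, and no-Dox replicate 3 gave 6, 1 higher and 5 lower, so the balance of directions turned. Leaving out Dox replicate 1 or 2 gave 0 genes, and Dox replicate 3 gave 1.

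Monocyte and macrophage markers were higher with Dox in wildtype marrow by camera, with a median of 0.79 over 18 members (adjusted p = 1.35e-08, and adjusted p = 0.122 with an estimated correlation). None passed over all genes, and 6 were higher adjusted over the list alone. Mrc1 was at 1.08 ± 0.27 and C1qc at 0.65 ± 0.14 (adjusted p = 0.393 and 0.273). NADPH oxidase and redox genes had a median of 0.16 (adjusted p = 0.211 with an estimated correlation) and STAT6 response genes 0.07 (0.261), with Retnla as the member passing and 4 adjusted over the list alone. Antigen presentation genes had a median of 0.11 (0.261), and ribosomal protein genes 0.06 (0.676). The STAT6, antigen presentation and ribosomal calls ended under both scalings. Neutrophil markers were lower, with a median of -0.28 and 16 of 17 members lower (adjusted p = 0.676 with an estimated correlation). Leaving out no-Dox replicate 3 gave 3 called lists and Dox replicate 1 gave 2.

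In knockout marrow 5 genes rose with Dox. They were Rnf138 at 1.41 ± 0.15 (SE, n = 3 and 3, adjusted p = 0.00755), Col14a1 at 1.40 ± 0.16 (adjusted p = 0.0110), Epb41l3, of the membrane skeleton, at 1.18 ± 0.15 (adjusted p = 0.0205), and the organic anion transporter gene Abcc3 at 1.07 ± 0.16 and Med23 at 0.80 ± 0.11 (adjusted p = 0.0477 each). Retnla was at 2.05 ± 0.50 (adjusted p = 0.138), the macrophage transcription factor gene Maf at 2.02 ± 0.33 (adjusted p = 0.0690), the efferocytosis receptor gene Mertk at 1.94 ± 0.37 and Epx at 1.60 ± 0.41, or 0.90 without the outlying array (adjusted p = 0.107). In each gene that passed, the 3 arrays with Dox lay wholly above the 3 without. The median over all genes was -0.13, which became -0.02 with median centring and -0.03 after quantile normalization. No gene was lower, and 6053 had an unadjusted p under 0.05. All 5 genes lost their call when only the groups compared were fitted, and with the Y-linked covariate Rnf138 and Col14a1 kept theirs. Rnf138 alone passed without the outlying array (adjusted p = 0.0314), with 2213 genes at an unadjusted p under 0.05. Leaving out no-Dox replicate 1 gave 346 genes, 117 higher and 229 lower, no-Dox replicate 2 gave 51, 29 higher and 22 lower, and Dox replicate 3 gave 0. With array weights 892 genes were higher and 2439 lower. After quantile normalization 117 genes were higher and 116 lower.

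Camera called 17 lists with Dox in knockout marrow, none with an estimated correlation, and fry called 3. The macrophage list had a median of 0.61 (adjusted p = 0.110 with an estimated correlation), with 4 members higher adjusted over the list alone and none over all genes. Cell cycle genes had a median of 0.66, with 35 of 38 higher (0.215), oxidative phosphorylation 0.65, with 30 of 33 higher (0.196), and housekeeping genes 0.56 (0.225). Without the outlying array the medians of macrophage, cell cycle and oxidative phosphorylation genes were 0.17, 0.12 and 0.13, and 8 lists were called. Smaller shifts upward were called for inhibitory receptors (0.35), neutrophil markers (0.30), granule genes (0.28), redox genes (0.18), lipid mediator genes (0.17), activating receptors (0.16), ribosomal proteins (0.15), apoptosis genes (0.08), glycolysis genes (0.02) and pattern recognition receptors (0.00). The activating and pattern recognition medians became -0.01 and -0.05 after quantile normalization. Chemoattractant receptors and interferon response genes were called higher with medians of -0.01 and -0.02, which were 0.02 and 0.07 after quantile normalization. For these 12 lists the adjusted p was 0.110 to 0.427 with an estimated correlation. Endothelial markers were lower at -0.24 (adjusted p = 0.380 with an estimated correlation), and fry also called dendritic cell markers lower at -0.29 (adjusted p = 0.0385).

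The largest differences separated esophageal from marrow eosinophils with Dox. In wildtype the esophageal cells had more Ptgs2, the inducible cyclooxygenase, by 5.94 ± 0.29 (SE, n = 3 and 3), Serpinb2, an inhibitor of plasminogen activators, by 5.82 ± 0.29, and Rnase2a, an eosinophil-associated ribonuclease, by 5.70 ± 0.29. Thbs1, which encodes thrombospondin 1, rose by 5.43 ± 0.23, the cytokine genes Il1a and Il1b by 5.06 ± 0.26 and 4.40 ± 0.42, and Ccrl2, an atypical chemoattractant receptor, by 4.90 ± 0.13. Marrow cells had more of the granule genes of immature granulocytes, with esophagus minus marrow differences of -6.33 ± 0.94 for Camp, -5.53 ± 0.10 for Ctsg and -5.45 ± 0.17 for Mpo. The eosinophil granule genes Prg3 (-5.22 ± 0.52), Prg2 (-3.53 ± 0.35) and Epx (-3.50 ± 0.41) were lower in the esophagus too, unlike Rnase2a. Each of these genes had adjusted p of 0.00111 or less and arrays wholly apart.

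In knockout the differences were 5.98 ± 0.29 for Ptgs2, 6.16 ± 0.29 for Serpinb2, 5.95 ± 0.29 for Rnase2a and -5.52 ± 0.17 for Mpo. Retnla rose by 3.68 ± 0.50 (adjusted p = 0.000406), Csf1 by 3.24 ± 0.22 (adjusted p = 1.37e-06) and Acod1, the enzyme that makes itaconate, by 5.46 ± 0.66. Siglecf rose by 1.14 ± 0.16 in knockout (adjusted p = 0.000479) and was at 0.32 ± 0.16 in wildtype (adjusted p = 0.165), and its genotype by tissue interaction was 0.82 ± 0.22 (adjusted p = 0.598). Ccr3 was at 0.64 in wildtype and 1.02 in knockout and did not pass in either.

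In wildtype 3366 genes passed, 1799 higher and 1567 lower in the esophagus, and in knockout 2336 passed, 997 higher and 1339 lower. Across all genes the differences in the 2 genotypes, which share no arrays, correlated with r = 0.84, where genes are not independent replicates. Of the genes called, 535 were higher in both, with 80.9 by chance overlap of independent lists, 925 were lower in both, with 94.6 by chance, and 1 went opposite ways. The wildtype median over all genes was 0.14, and median centring lowered it to 0.03 and changed the wildtype counts to 1185 higher and 1738 lower. After quantile normalization it was 0.05, with 803 higher and 1245 lower, and with the Y-linked covariate 1629 genes passed in wildtype. Without the outlying array 8092 genes passed in wildtype, 5569 higher and 2523 lower, including all 3366. In knockout 4175 then passed, 2163 higher and 2012 lower, including all 2336. In wildtype, leaving out marrow replicates 1, 2 and 3 gave 1335, 1750 and 1988 genes, and leaving out esophageal replicates 2 and 3 gave 1924 and 2105, each with more genes lower than higher. In knockout, leaving out marrow replicate 1 gave 1538.

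**Figure D3:**
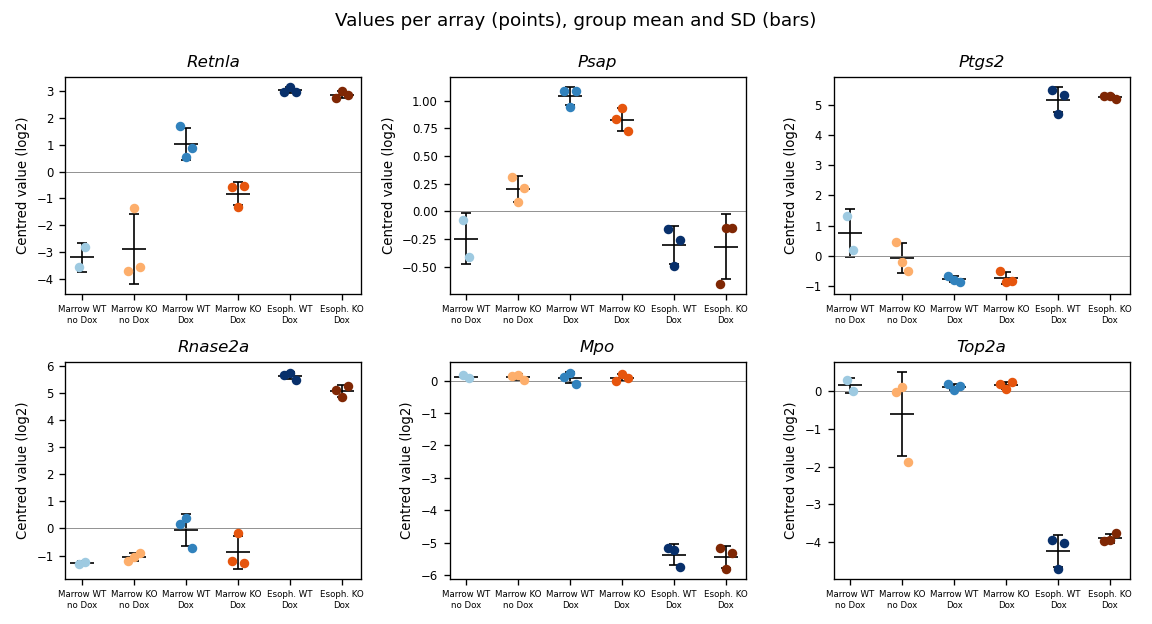
Centred log2 values of Retnla, Psap, Ptgs2, Rnase2a, Mpo and Top2a, with a point per array and bars for the mean and SD of each of the 6 groups. Retnla averages -3.20 in wildtype marrow without Dox, 1.03 with Dox and 3.03 in the wildtype esophagus.

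NF-kB response genes were higher in the esophagus, with 20 of 31 members passing in wildtype and 19 in knockout, none lower (adjusted over the list alone, 21 higher and 1 lower, and 23 higher). The NF-kB inhibitors Tnfaip3 and Nfkbia rose by 4.01 ± 0.22 and 1.92 ± 0.12 in wildtype. The list medians were 0.98 and 1.51, with adjusted p = 0.00906 and 0.000499 with an estimated correlation. Immediate-early and dissociation response genes rose in 24 of 33 cases in each genotype (26 and 27 adjusted over the list alone), with medians of 1.24 and 1.74. Dusp1, a phosphatase of MAP kinases, rose by 2.30 ± 0.11 in wildtype. Esophageal and marrow cells were released in different ways, the former by collagenase.

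Chemokine genes rose in 12 of 26 cases in wildtype and 9 in knockout (13 and 10 adjusted over the list alone), with medians of 0.83 and 0.79. Cxcl2, a neutrophil attractant, rose by 4.44 ± 0.26 in wildtype and 5.05 ± 0.26 in knockout, and Ccl3 by 3.44 ± 0.44 and 4.32 ± 0.44. Cytokines and growth factors had 13 members higher and 2 lower in each genotype, and adjusted over the list alone 21 higher and 2 lower in wildtype and 15 higher and 3 lower in knockout. Their medians were 0.36 and 0.25. Matrix and protease genes had 13 higher and 1 lower in wildtype and 12 and 1 in knockout (16 and 1, and 13 and 1, adjusted over the list alone), with medians of 0.47 and 0.25. Fn1, which encodes fibronectin, rose by 2.58 ± 0.26 in wildtype. STAT5 response genes, downstream of IL-5, had 12 higher and 1 lower in wildtype and 12 and 2 in knockout (14 and 2, and 16 and 3, adjusted over the list alone). Their medians were 0.42 and 0.47, and Cish, a feedback inhibitor of STAT5, rose by 1.81 ± 0.26 and 2.37 ± 0.26. The immediate-early, chemokine, cytokine, matrix and STAT5 lists held in both genotypes with an estimated correlation, with adjusted p = 0.0304 in wildtype and from 0.00388 to 0.0117 in knockout. In that order, 4 of 33, 10 of 26, 6 of 33, 5 of 30 and 14 of 30 members also lie in another list. For the NF-kB list 15 of 31 do, so these calls are not independent of one another. Chemoattractant receptors were called higher too, with 11 and 13 of 29 members passing and none lower (14 and 17 adjusted over the list alone). Their medians were 0.64 and 1.02, with adjusted p = 0.0642 in wildtype and 0.00388 in knockout with an estimated correlation. Ptafr, the receptor of platelet-activating factor, rose by 2.03 ± 0.26 and 2.77 ± 0.26.

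Cell cycle genes were lower in the esophagus, with 35 of 38 members passing in wildtype and 33 in knockout (36 and 35 adjusted over the list alone). Their medians were -2.22 and -2.40, with adjusted p = 0.0304 and 0.0128 with an estimated correlation. Rrm2, of ribonucleotide reductase, was at -3.30 ± 0.22 in wildtype and -3.46 ± 0.22 in knockout, and Top2a, the mitotic topoisomerase, at -4.36 ± 0.39 in wildtype. Granulocyte progenitor markers fell in 9 of 14 cases in wildtype and 10 in knockout, with the same counts adjusted over the list alone and medians of -1.53 and -1.62. They held with an estimated correlation (adjusted p = 0.00784 and 0.00291). Myb, a transcription factor of progenitors, was at -3.74 ± 0.21 and -3.49 ± 0.21. Neutrophil markers had 9 members lower and 1 higher in wildtype and 11 lower and 2 higher in knockout (12 and 2, and 11 and 2, adjusted over the list alone), with adjusted p = 0.0618 and 0.0892 with an estimated correlation. Ribosomal protein genes had 6 of 29 members lower in each genotype (8 and 10 adjusted over the list alone), with medians of -0.38 and -0.47 and adjusted p = 0.0304 and 0.0314 with an estimated correlation. Oxidative phosphorylation genes had medians of -0.85 and -0.77, with 7 and 5 of 33 lower (12 in each adjusted over the list alone), and adjusted p = 0.0967 and 0.124 with an estimated correlation. Atp5b, of the ATP synthase, was at -1.20 ± 0.17 and -0.98 ± 0.17.

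Among marker lists, monocyte and macrophage markers were lower in the esophagus, with 3 of 18 members passing in wildtype and 10 in knockout (3 lower, and 12 lower and 1 higher, adjusted over the list alone). Their medians were -0.27 and -0.74, with adjusted p = 0.142 and 0.0314 with an estimated correlation. Mertk was at -2.94 ± 0.37 and -3.06 ± 0.37, and Mrc1 at -1.60 ± 0.24 in knockout. Mast cell and basophil markers had 4 members lower in each genotype, and adjusted over the list alone 5 lower and 3 higher in wildtype and 4 lower in knockout. The mast cell protease gene Cpa3 was at -3.87 ± 0.35 and -3.97 ± 0.35. The wildtype median of that list was 0.09, against its test, and -0.02 under both scalings, and adjusted p was 0.234 and 0.124 with an estimated correlation. Fibroblast markers had 4 of 15 members higher in each genotype (7 and 6 adjusted over the list alone), with medians of 0.42 and 0.45 and adjusted p = 0.148 and 0.0705 with an estimated correlation. Muscle markers had medians of 0.35 and 0.27, with 1 and 5 of 17 members higher over all genes and over the list alone, and adjusted p = 0.327 and 0.183 with an estimated correlation. In knockout alone, camera called dendritic cell markers (0.37, with adjusted p = 0.149 with an estimated correlation) and squamous epithelium markers (0.22, 0.408) higher, and erythroid markers (-0.26, 0.0314) lower. The wildtype medians of these lists were 0.31, 0.31 and -0.11, and whether the genotypes differ in them was tested in the interaction, which called none of the 3. Not called in either genotype were T and NK cell markers (0.22 in wildtype and 0.12 in knockout), B and plasma cell markers (0.02, or -0.06 after quantile normalization, and -0.06), megakaryocyte markers (0.30 and 0.26) and endothelial markers (0.15 and 0.05).

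STAT6 response genes had 12 members higher and 3 lower in wildtype and 7 higher and 5 lower in knockout (17 and 4, and 11 and 5, adjusted over the list alone). Their medians were 0.48 and 0.31, with adjusted p = 0.0967 and 0.0623 with an estimated correlation, and the wildtype camera call ended without the outlying array (adjusted p = 0.112). Tgm2, a transglutaminase, rose by 3.15 ± 0.35 and 4.07 ± 0.35. Granule and identity genes were called higher in knockout, with 9 higher and 4 lower of 26 and a median of 0.69 (12 and 4 adjusted over the list alone, and adjusted p = 0.124 with an estimated correlation). In wildtype they had 7 higher and 3 lower (8 and 5 adjusted over the list alone) and a median of 0.40, and were not called (adjusted p = 0.867). The members that fell in wildtype were the granule genes Epx, Prg2 and Prg3, and those that rose included Trib1, a pseudokinase, at 2.56 ± 0.28 and 3.11 ± 0.28. Lipid mediator genes (0.30 in wildtype and 0.07 in knockout, adjusted p = 0.0705 in knockout with an estimated correlation) and glycolysis genes (0.03, or -0.03 and -0.07 under the scalings, and 0.17, adjusted p = 0.213) were called higher in knockout alone. Both calls ended after quantile normalization, and the interaction with genotype was called for glycolysis but not for lipid mediator genes. Hpgd was at -2.29 ± 0.27 and -3.22 ± 0.27, and the glucose transporter gene Slc2a1 rose by 1.05 ± 0.13 and 1.43 ± 0.13.

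Housekeeping genes were lower in the esophagus by camera, with medians of -0.67 and -0.51 and 3 and 1 of 12 members passing (3 and 2 adjusted over the list alone), and adjusted p = 0.142 and 0.287 with an estimated correlation. Gapdh fell by 0.56 in wildtype, and by 0.49 and 0.66 after quantile normalization and median centring. Lists not called in either genotype were inhibitory receptors (medians of -0.04 and 0.15), activating receptors (0.33 and 0.32), redox genes (0.05, or -0.04 and -0.05 under the scalings, and 0.10), interferon response (-0.18 and -0.14), apoptosis (0.19 and 0.08), antigen presentation (0.14 and 0.17), pattern recognition receptors (0.04, or -0.07 with median centring, and 0.11) and genes near the targeted gene on chromosome 7 (0.25 and 0.10). The wildtype tests of the activating receptor, redox, pattern recognition, glycolysis and B cell lists, and the knockout test of the redox list, pointed down, against their medians. Members passing in wildtype were 2 higher and 2 lower of 26 inhibitory receptor genes, 7 and 5 of 29 activating receptor genes, 3 and 3 of 19 redox genes and 1 and 4 of 31 interferon genes. They were 7 and 1 of 29 apoptosis genes, 4 and 2 of 22 antigen presentation genes, 5 and 1 of 30 pattern recognition genes and 4 and 4 of 31 chromosome 7 genes. In the same order they were 5 and 1, 7 and 4, 5 and 2, 3 and 0, 7 and 1, 3 and 1, 6 and 4, and 4 and 3 in knockout. Adjusted over the list alone they were 2 and 2, 8 and 6, 4 and 7, 2 and 5, 9 and 2, 4 and 2, 5 and 2, and 8 and 5 in wildtype, and 5 and 1, 9 and 5, 5 and 4, 3 and 0, 7 and 2, 3 and 2, 6 and 4, and 4 and 3 in knockout. Of the inhibitory receptor genes, Lilrb4a rose by 2.69 ± 0.53 in wildtype and 3.04 ± 0.53 in knockout, while Clec4a3 was at -2.63 ± 0.43 in wildtype (adjusted p = 0.00191) and Lair1 at -1.59 ± 0.37 and -1.48 ± 0.37 (adjusted p = 0.0144 and 0.0209). The immune checkpoint ligand gene Cd274 rose by 2.40 ± 0.20 and 3.12 ± 0.20, the death gene Bcl2l11 by 2.62 ± 0.22 and 2.68 ± 0.22, and the costimulator gene Cd80 by 2.95 ± 0.35 and 4.12 ± 0.35. Hmox1 was at -1.78 ± 0.24 and -2.57 ± 0.24.

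**Figure D4:**
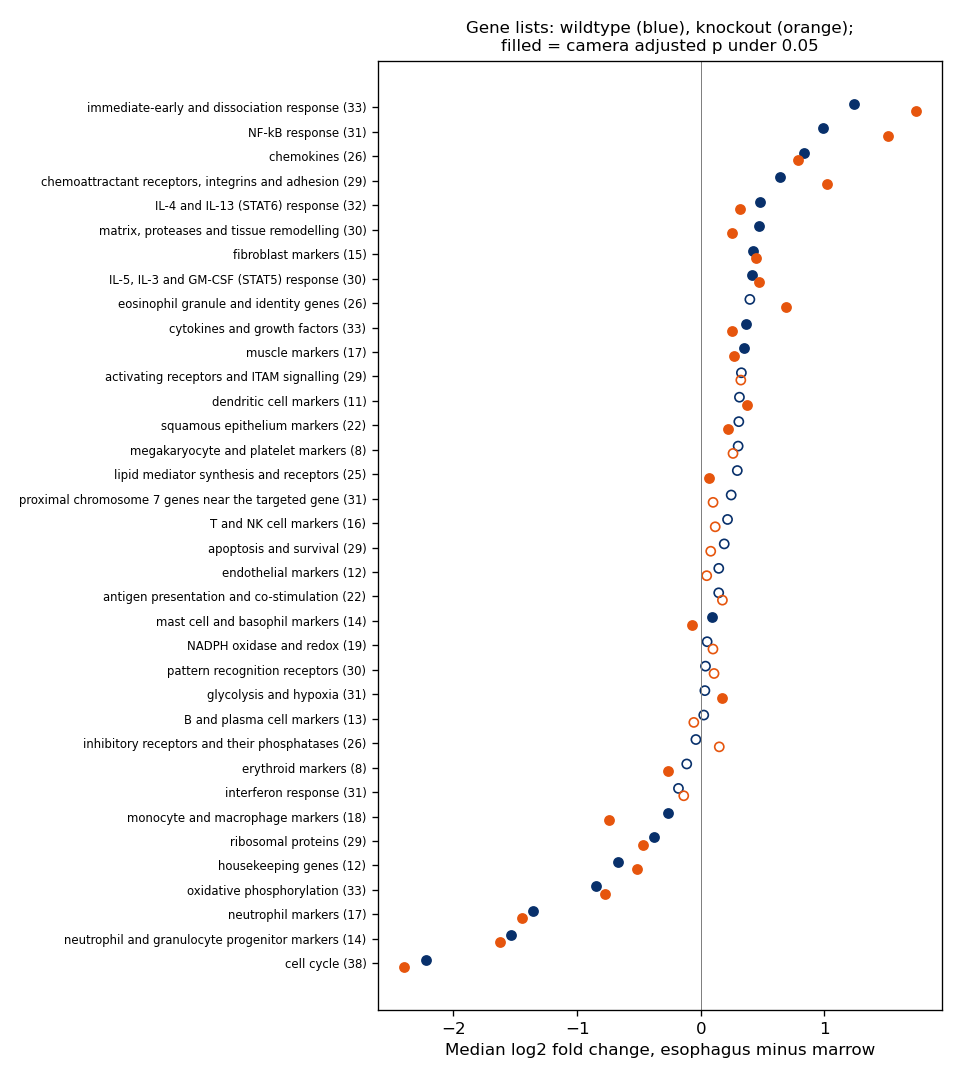
Median log2 difference, esophagus minus marrow with Dox, of the 36 gene lists, in wildtype (blue) and knockout (orange), with filled points for a camera adjusted p under 0.05 and the number of members in parentheses. Cell cycle genes lie lowest, at -2.22 and -2.40, and immediate-early genes reach 1.24 and 1.74.

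The interactions test whether the genotype effect differs between tissues or with Dox. Between tissues 1 gene passed by limma, with 1099 at an unadjusted p under 0.05. It was Suz12, whose genotype effect was 1.60 ± 0.16 larger in the esophagus than in marrow (SE, 12 arrays, adjusted p = 0.00502). Its call ended after quantile normalization (0.74, adjusted p = 0.922) and with trend and robust moderation (adjusted p = 0.782). The first of these settings narrows esophageal values by construction. Csf1 (2.02 ± 0.31, adjusted p = 0.165), Adamdec1 (2.44 ± 0.40, adjusted p = 0.194), Phlda1 (1.38 ± 0.24, adjusted p = 0.242), Tnf (2.37 ± 0.57, adjusted p = 0.541) and Tmem141 (-1.51 ± 0.23, adjusted p = 0.164) did not pass, so the genotype effects in these genes are not shown to differ between tissues. Without the outlying array 12 genes passed, 10 higher and 2 lower. Leaving out wildtype esophageal replicates 1, 2 and 3 gave 34, 7 and 2, knockout esophageal replicates 2 and 3 gave 4 and 6, and wildtype marrow replicate 2 gave 2.

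Camera called 14 lists in the tissue interaction, 4 of them also with an estimated correlation, and fry none. The 4 were granule and identity genes (0.30, adjusted p = 0.0477 with an estimated correlation), chemoattractant receptors (0.38, 0.0338), NF-kB response (0.32, 0.0273) and glycolysis and hypoxia (0.28, 0.0273). The first 2 lost their camera call after quantile normalization (adjusted p = 0.199 and 0.302). Leaving out knockout marrow replicate 2 or wildtype esophageal replicate 2 gave 9 lists, and the Y-linked covariate gave 3. For the genotype by Dox interaction in marrow no gene passed by limma, with 1391 at an unadjusted p under 0.05, and the median over all genes was -0.12, or -0.01 with median centring. Rnf138 was at 1.55 ± 0.22 and Alg6, of the N-glycosylation pathway, at 1.32 ± 0.21 (adjusted p = 0.215 each). Med23 was at 1.00 ± 0.17 (adjusted p = 0.333), Zfp740 at 1.05 ± 0.19 and Ccdc18 at 1.80 ± 0.35. The count was also 0 without the outlying array, with 972 at an unadjusted p under 0.05. Leaving out no-Dox wildtype replicates 1 and 3 gave 2 and 4 genes, and wildtype Dox replicate 1 gave 1. Camera called 9 lists there, with an estimated correlation none, and fry none. Camera called 0 lists without the outlying array, 1 of the 3 knockout arrays without Dox, and without knockout no-Dox replicate 1 it called 14.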

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

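The tests of array quality, macrophage RNA, progenitors and tissue digestion were chosen only after the results were seen, while the counts of other splits of the arrays were planned.

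Csf1, Adamdec1, Ikzf2 and Siglecf are among the 77 genes that differed by genotype in the esophagus, and a difference in the quality of the wildtype arrays is a candidate explanation. Of the 763 genes called without the outlying array, 82.8% deviated in that array, against its group mates, in the direction of the wildtype esophageal arrays, and across all genes the correlation was -0.44, so quality may account for part of them. Of the 77 genes, 46.8% did so, but the outlying array deviated less over them (median size 0.208) than over all genes (0.379), so quality and genotype cannot be told apart there. Only 30.1% of all genes were lower in the outlying array, the direction that 69 of the 77 would need. An even split is therefore not the share to read 46.8% against. With a Y-linked covariate for sex 7 genes passed, Csf1 among them (2.20, adjusted p = 0.0323). All 77 differences kept their direction, while their median size went from 1.29 to 1.12 and their median SE from 0.205 to 0.251. The Csf1 call thus stayed beyond a linear trend with the mean of the Y-linked genes. That mean is an imperfect measure of sex. Its genes differed between the esophageal genotypes by 0.04 (Eif2s3y), 1.34 (Kdm5d) and 0.88 (Uty). Sex is therefore not excluded as a cause for Csf1. Of the covariate's genes, Kdm5d was also low in the outlying array, at -1.66 against 0.03 and -0.03 in its group mates. Uty was at -0.49 against 0.02 and -0.29, and Eif2s3y at -0.03 lay between its mates, at 0.25 and -0.20. Xist ran from -0.11 to 0.21 over the 17 arrays, with 0.21 in the outlying array. The covariate may follow array quality as well as sex, which cannot be told apart for the genes that lost their call. Macrophage RNA in the wildtype arrays would raise genes there, while 69 of the 77 genes were higher in knockout. Its direct addition could therefore bear only on the 8 lower genes. Whether it also lowered the share of eosinophil RNA in the wildtype arrays was not tested, so it stays open for all 77. The macrophage list, with 5 of 18 members in another list, had a median of -0.17 (adjusted p = 0.216 by camera). Its transcripts Lyz2 and Apoe were at -0.33 and -0.28, and the gate on Siglec-F and CCR3 should remove macrophages.

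Esophageal eosinophils had less Mpo, Ctsg, Epx and Top2a and more Ptgs2 and Dusp1 than marrow eosinophils. Progenitor markers, with 2 of 14 members in another list, had medians of -1.53 in wildtype and -1.62 in knockout, which other granulocytes in the marrow gate could give, but Epx and Prg2 were lower too and immature eosinophils express these genes, so the 2 sources cannot be told apart. Immediate-early genes had medians of 1.24 and 1.74, which collagenase digestion could give, but only the esophagus was digested, so digestion and tissue cannot be told apart. In the outlying marrow array Epx was at -1.57, against 0.72 and 0.34 in its group mates, and Top2a at -1.88, against -0.02 and 0.11. Both lay toward the esophageal values. Mpo at 0.0075, against 0.15 and 0.17, and Ptgs2 at -0.50, against 0.47 and -0.20, stayed far from theirs. Array quality was not tested for the tissue difference. Tissue itself stays a possible biological cause and was not tested apart from these. Of 10 splits, 1 (the real one) gave 3366 genes in wildtype and 2336 in knockout, with 0 as the highest other in each, too few splits for a share under 0.05.

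The macrophage list was called higher by camera with Dox in marrow, with no member passing over all genes, which RNA from macrophages in the sorted cells could give. The median over Lyz2, Apoe, C1qa, C1qb, C1qc and Cd68 was 0.53 in wildtype and 0.086 in knockout, with Lyz2 at -0.10 and -0.01 and Cd68 at 1.02 and 0.85. The list was not called with an estimated correlation (adjusted p = 0.122 and 0.110), and the gate should remove macrophages, so RNA from them and a response of the eosinophils to Dox cannot be told apart. Of 10 splits in knockout, 1 (the real one) called 5 genes with Dox and the highest other called 0, too few splits for a share under 0.05.

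For the genotype effect in the esophagus, 1 of the 10 splits of the 6 arrays, the real one, gave 77 genes and the highest other gave 8, too few splits for a share under 0.05. For the genotype effect in marrow with Dox and for its average over the 3 settings the real count was 0, which all 10 and all 100 drawn splits reach by construction, so the splits decide nothing there. The highest other counts were 1 and 4. For the tissue interaction, 9 of 100 drawn splits gave at least the 1 real gene, with 2 as the highest, so chance was not excluded.

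The genotype by tissue interaction passed its test for Suz12 (1.60, lost after quantile normalization with adjusted p = 0.922), and camera called it for 14 lists, while fry called none. Their interaction medians were 0.30 for granule and identity genes, 0.24 for inhibitory receptors, 0.15 for activating receptors, -0.0602 for cytokines (0.00 with median centring), 0.38 for chemoattractant receptors, 0.0232 for matrix genes and 0.18 for redox genes. They were 0.32 for NF-kB response, 0.38 for immediate-early genes, 0.28 for glycolysis, 0.0469 for antigen presentation, 0.32 for neutrophil markers, -0.30 for macrophage markers and 0.15 for housekeeping genes. Besides the granule, chemoattractant, NF-kB and glycolysis lists, these had adjusted p of 0.166 to 0.466 with an estimated correlation. The genotype by Dox interaction in marrow was called by camera for 9 lists, and for 0 without the outlying array. With all arrays the medians were 0.0752 for granule genes, 0.30 for inhibitory receptors, 0.27 for activating receptors, 0.21 for chemoattractant receptors, 0.0522 for lipid mediators, 0.67 for cell cycle, 0.46 for oxidative phosphorylation, 0.68 for neutrophil markers and 0.42 for housekeeping genes. With an estimated correlation these had adjusted p of 0.224 to 0.483.

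Signals were also present in the 10272 probe sets with several gene symbols or none, which no comparison used. Of these, 12 passed for genotype in the esophagus, 3 for genotype in marrow with Dox and 11 without Dox, 27 for Dox in wildtype marrow and 1 in knockout, 670 for tissue in wildtype and 354 in knockout, and 3 for the tissue interaction. None passed for the averaged genotype effect or the Dox interaction.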

How the results depend on the processing

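Leaving out the outlying array and using the probe set with the lowest number were chosen after seeing the data, and all other alternatives were planned. Of 203 called values of named genes, none reversed under any setting. Calls lost were 39 with only the groups compared, 31 with the Y-linked covariate, 30 after quantile normalization, 25 with trend and robust moderation, 23 with a fold threshold, 21 with the replicate block, 12 with median centring, 5 with the lowest probe set number and 0 with array weights. Leaving out 1 array at a time lost 149 of 1219. Most of the 203 were tissue calls, of which 6 of 86 in wildtype and 4 of 84 in knockout were lost without at least 1 array. The esophageal genotype lost 20 of 22, Dox lost 5 of 5 in each genotype, and the tissue interaction lost 0 of 1. In the order esophageal genotype, marrow genotype with Dox, marrow genotype without Dox, averaged genotype, Dox in wildtype, Dox in knockout, tissue in wildtype, tissue in knockout, tissue interaction and Dox interaction, counts of genes without 1 array of the groups compared ranged 22 to 532, 0 to 2, 0 to 6, 0 to 3, 0 to 14, 0 to 346, 1335 to 4243, 1538 to 1741, 1 to 34 and 0 to 4. Counts of lists without 1 such array ranged 14 to 17, 0 to 2, 2 to 12, 0 to 13, 2 to 7, 8 to 18, 17 to 20, 21 to 26, 9 to 16 and 0 to 14. Where an array of the 2 without Dox was left out, the lone array was assumed to vary like the other groups.

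Counts that moved by more than 1.5 times are listed by setting, and the cause was not tested except where fewer calls follow from the setting itself. With a log2 fold of at least 1, the esophageal genotype kept 51 genes, tissue 1354 in wildtype and 1323 in knockout. With trend and robust moderation the esophageal genotype had 30, Dox 1 in wildtype and 0 in knockout, and the tissue interaction 0. With only the groups compared, on fewer arrays, the esophageal genotype had 8, Dox 0 in each genotype, tissue in knockout 4451 and the tissue interaction 5. Array weights gave 858 for esophageal genotype, 6 for marrow genotype with Dox, 2 averaged, 55 and 3331 for Dox in wildtype and knockout, 8210 and 6117 for tissue, 35 and 3 for the tissue and Dox interactions. Quantile normalization gave 2 for esophageal genotype, 37 for marrow genotype without Dox, 126 and 233 for Dox, 2048 for tissue in wildtype and 0 for the tissue interaction. It narrows esophageal and widens most marrow values by the setting itself, so these counts cannot separate scaling from effect. Median centring gave 3 for Dox in wildtype. The Y-linked covariate gave 7 for esophageal genotype, 2 and 2 for Dox and 1629 for tissue in wildtype. Without the outlying array there were 763 for esophageal genotype, 1 for marrow genotype without Dox, 2 averaged, 33 and 1 for Dox in wildtype and knockout, 8092 and 4175 for tissue and 12 for the tissue interaction.

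With the replicate number as a block, the esophageal genotype had 47 genes, marrow genotype with Dox 1 and Dox in wildtype 2. For the tissue difference and the tissue interaction, the block was each replicate number within a genotype. It was fitted to the arrays with Dox alone, which leaves out the outlying array. Tissue in wildtype then had 5528 genes and the tissue interaction 0 (Suz12 at 1.60, adjusted p = 0.344). Leaving out the outlying array without a block gave 8092 for tissue in wildtype, so the effect of the block alone is not shown there. No other count moved by more than 1.5 times. No label says whether same-numbered marrow and esophageal arrays of 1 genotype come from 1 animal. The main tissue tests used no pairing and would ignore it. Deviations of these arrays with Dox correlated across genes at 0.12, -0.04 and 0.04 in wildtype. In knockout the correlations were 0.02, -0.06 and -0.03. Same-numbered arrays correlated at 0.06, -0.09 and 0.05 between the esophageal genotypes. Between the marrow genotypes with Dox they correlated at 0.03, 0.01 and 0.01. In these 2 comparisons 2 and 3 of the 6 arrays correlated best with their own number. Over all 40 same-numbered pairs the correlations ran from -0.0999 to 0.230, with 11 over 0.1. None of the 10 pairs of groups with 3 shared numbers had all over 0.1. Of the 5 with 2 shared numbers 2 did, with 0.18 and 0.20 between the marrow genotypes without Dox and 0.14 and 0.18 between wildtype marrow without and with Dox.

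For lists, an estimated correlation left 4 for esophageal genotype, 0 for marrow genotype with and without Dox, 0 for Dox in each genotype, 9 and 12 for tissue, 4 for the tissue interaction and 0 for the Dox interaction. Fry called 6 for esophageal genotype, 0 for marrow genotype with and without Dox, 0 and 3 for Dox, and 0 for both interactions. Leaving out the outlying array gave 2 lists for marrow genotype without Dox, 13 averaged, 8 for Dox in knockout, 20 for tissue in knockout (24 with all arrays) and 0 for the Dox interaction. Array weights gave 2 for marrow genotype with Dox, 1 without Dox, 9 averaged, 9 for Dox in knockout and 1 for the Dox interaction. Quantile normalization gave 7 for esophageal genotype, 0 and 3 for marrow genotype with and without Dox, 3 averaged, 5 for the tissue and 2 for the Dox interaction. The Y-linked covariate gave 4 for esophageal genotype, 0 for marrow genotype with Dox, 5 averaged, 2 and 11 for Dox, and 3 and 5 for the interactions. A stricter filter, no filter and a floor for low values were not run, because centred values hold no brightness, and for the same reason signal over background is unknown. The planned mean of all probe sets became the main rule.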

Other observations

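All values below were chosen for description only after they were seen, and no explanation of them was tested.

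Retnla and Rnase2a, which encode secreted proteins of the type 2 response, were highest in esophageal cells in both genotypes. The centred mean of Retnla was -3.20 without Dox, 1.03 in marrow with Dox and 3.03 in the esophagus, and in knockout -2.88, -0.82 and 2.86. Rnase2a was at -1.26, -0.06 and 5.64 in wildtype and -1.06, -0.88 and 5.08 in knockout. For Retnla the Dox effect in marrow passed in wildtype (adjusted p = 0.0289) and not in knockout (adjusted p = 0.138), and the tissue difference passed in wildtype (adjusted p = 0.0206) and in knockout (adjusted p = 0.000406). The tissue difference of Rnase2a passed in both genotypes (adjusted p = 8.69e-08 and 5.15e-08), and its Dox effect in neither (adjusted p = 0.526 and 0.657).

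The genotype effects in the esophagus and in marrow with Dox, which share no arrays, correlated across genes with r = 0.22. The Dox effects in wildtype and knockout marrow, which share none either, correlated with r = 0.28. For genotype effects in marrow with and without Dox r was -0.22. Genes are not independent replicates, so no p-value is given.

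In 118 probe sets shared by several genes, all genes found in the reference gene table lie on the Y chromosome. Of these, 26 were lower with Dox in wildtype marrow. Without Dox, 11 were lower in knockout than in wildtype marrow, all 11 in both. Both contrasts use the same 2 wildtype marrow arrays without Dox. The mean of the 26 was 0.53 and 0.66 in these 2 arrays, and -0.12 to 0.16 in the 15 other arrays. The 26 were chosen by their difference from these 2 arrays, so that height follows from the choice.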
